A study of Mus musculus with 23 samples.

How the data were processed

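The authors' tables hold signal of the kind their headers call normalized counts, with 24421 genes and one column per library. Their processing notes name cutadapt, TopHat2 2.0.10, HTSeq 0.6.1p1, DESeq2 1.6.3 and genome build mm10, without saying what each did. The gene annotation, the strandedness of the libraries and the way blood was drawn are not given in the sources used here. In each of the 23 libraries 100% of the values were whole multiples of one step, within a tolerance of 0.001, so the values are reads divided by one factor per library. The largest factor was 1.301 times the smallest in CT26 and 1.464 times in B16. In order of day and replicate the CT26 libraries held 10.7e6, 10.78e6, 10.76e6, 11.99e6, 11.67e6, 11.36e6, 11.96e6, 12.04e6, 12.48e6, 11.82e6, 14.27e6 and 13.34e6. The B16 libraries held 13.46e6, 13.55e6, 13.81e6, 14.17e6, 13.94e6, 12.39e6, 12.46e6, 12.53e6, 14.89e6, 14.98e6 and 15.03e6 normalized counts. Each tumour model was normalized on its own, so levels were not compared between models.

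Tests, gene lists and alternatives were chosen before the data were examined, except those named as added. They assumed read counts and named a fallback for normalized values, and the fallback is what was used. limma 3.58.1 in R 4.3.3 was run with a trend on log2(value + 1), one fit per model with a mean for each day, over genes with a mean of at least 5 (11373 in CT26, 11930 in B16), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All libraries of a model share one variance estimate and the day 0 libraries enter every comparison with day 0, so those comparisons are not independent of each other. Named genes are the 8 called genes with the largest fold change in each direction and a mean of at least 5 in one group, then Arg1, Nos2, S100a8 and S100a9 whether called or not, and up to 4 members of each list. Ly6g was planned as well and is not analysed here. Some genes chosen by these rules are not reported here.

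Lists were tested with camera at a preset correlation between genes of 0.01 and a minimum of 3 members. Of 31 lists 29 could be tested. The mitochondrially encoded genes and the basophil and mast cell markers had too few members. Lists called numbered 14, 15 and 17 in CT26 and 10, 9 and 11 in B16 at days 4, 8 and 11. The lists were written from general knowledge, and a list's name says what its genes are known for, not what the cells did. The photoreceptor, tissue macrophage, fibroblast and Rn45s lists were added after the values were seen and were counted, not tested. Reads of gene families with near-identical members (Ear1, Ear2 and Ear6, the Stfa genes, Ifit3 and Ifit3b, the Wfdc genes, histone and H2 genes) cannot be placed with certainty, and H2 genes also differ between the mouse strains.

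Reads recovered from the steps were used for count tests with edgeR 4.0.16, DESeq2 1.42.0 and limma-voom as alternatives. In 4 CT26 libraries (day 0 replicate 3, day 4 replicates 2 and 3, day 8 replicate 1) the step lies near 1 and the recovery was not accepted, so these tests used 8 CT26 libraries and 11 B16 libraries. On these the edgeR test with TMM called 74 genes for CT26 day 4 against day 0, where 1 day 4 library is assumed to vary like the others, and 1405 for CT26 day 8 against day 0. The test between models had been planned for counts in both tables, and was run only in this form. At day 4 it would rest on 1 CT26 library, so it is not used here. Coordinates are from a GRCm38 annotation, in which 408 of 411 names were found once. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

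In simulated values with 200 changed genes in each model the limma test at day 8 recovered, for folds of 1.5, 2 and 4, 16.4%, 72.7% and 95.5% in CT26 and 34.8%, 78.5% and 100% in B16, and called 5 and 7 unchanged genes. Over the changed genes of both, 132, 129 and 126 of them tested, the joint test recovered 3.03%, 38.8% and 85.7% and called 12 unchanged genes. Without changed genes the day 11 tests called 0 in both models (limma). A shifted list was called with adjusted p = 1.71e-30 in CT26 and 2.03e-44 in B16, or 2.52e-05 and 0.000177 with an estimated correlation. The 1 and 0 other lists called give no error rate for real libraries, which called up to 15 with days mixed.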

Results

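Gene expression was measured by poly-A RNA sequencing in immature myeloid cells, a mixed population of neutrophil-like and monocyte-like cells also called myeloid-derived suppressor cells, that were separated from mouse blood with magnetic beads. Blood was taken at days 0, 4, 8 and 11 of tumour growth in 2 models. CT26 is a colon carcinoma line grown in BALB/c mice and B16 is a melanoma line grown in C57BL mice. The question put to these data was which transcripts in circulating immature myeloid cells change as a tumour grows. The sources describe 3 biological repeats per group and do not say beyond that whether the libraries of one group came from separate animals. There were 12 CT26 libraries and 11 B16 libraries, because B16 day 4 had 2. Values are normalized counts, that is gene read counts divided by one factor per library, and each tumour model was normalized on its own. Group values are given as mean ± SD over 3 libraries, or over 2 at B16 day 4, and changes as log2 fold change ± standard error.

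The libraries held 10.7e6 to 14.27e6 normalized counts in CT26 and 12.39e6 to 15.03e6 in B16. The calgranulin genes S100a8 (chromosome 3, 90668978 to 90670035, plus strand) and S100a9 (chromosome 3, 90692632 to 90695721, minus strand), which neutrophils and monocytes express strongly, made up 2.13% to 4.11% of the counts of a CT26 library and 2.4% to 3.88% of those of a B16 library. S100a9 was the largest gene of every library but the 3 of B16 day 0, where the 45S ribosomal RNA precursor gene Rn45s took 2.57%, 2.63% and 3.1%. Rn45s took 0.427% to 1.05% of the later B16 libraries and 0.343% to 0.77% of the CT26 libraries, so the B16 day 0 libraries stand apart in every B16 comparison with day 0. The first 2 principal components held 54.1% and 13.9% of the variance in CT26 and 43.9% and 22% in B16. CT26 day 11 replicate 1 stood at 37.9 on the second, against -26.1 and -18.8, and the B16 day 4 libraries at 29.9 and -10.3 on the first. Libraries of one day correlated with r of 0.975 to 0.9915 in CT26 and 0.9746 to 0.9909 in B16, and libraries of different days with 0.922 to 0.9813 and 0.9253 to 0.9776, across genes, which are not independent replicates.

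At day 4 of CT26 growth Mx2 rose and Cxcl2, Ptgs2 and Fosb fell, while S100a8 and S100a9 were not called. Mx2, an interferon-induced antiviral GTPase gene, rose from 15.7 ± 2.52 to 122 ± 7.34 (log2 2.89 ± 0.26, adjusted p = 1.68e-06). Cxcl2, a neutrophil-attracting chemokine gene, fell from 658 ± 73.9 to 43.4 ± 6.04 (log2 -3.89 ± 0.29, adjusted p = 2.13e-07). Ptgs2, the inducible prostaglandin synthase gene, fell from 2874 ± 229.9 to 667 ± 73.8 (log2 -2.11 ± 0.12, adjusted p = 1.1e-08), and the transcription factor gene Fosb fell from 2795 ± 241 to 586 ± 57.6 (log2 -2.25 ± 0.11, adjusted p = 2e-09). S100a8 stood at 76190 ± 14840 and 84130 ± 5364 (log2 0.16 ± 0.18, adjusted p = 0.589) and S100a9 at 203000 ± 41930 and 210400 ± 13610 (log2 0.07 ± 0.20, adjusted p = 0.85). Arg1, the arginase gene of suppressor cells (chromosome 10, 24915221 to 24927484, minus strand), was near the floor on both days and not called (log2 -0.28 ± 0.70, adjusted p = 0.829), and neither was Nos2, the inducible nitric oxide synthase gene (chromosome 11, 78920787 to 78960254, plus strand, log2 1.17 ± 0.52, adjusted p = 0.152).

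The largest rises of CT26 day 4 were partly in genes of other tissues. The polarity gene Pard3 went from 0.921 ± 0.887 to 303 ± 244 (log2 7.03 ± 0.77, adjusted p = 1.71e-05), with 82.2 to 565 in the day 4 libraries and at most 6.14 in any other CT26 library. The photoreceptor gene Gnat1 went from 1.88 ± 1.64 to 114 ± 75.6 (log2 5.26 ± 0.68, adjusted p = 8.94e-05), and was listed at 0 on days 8 and 11. The photoreceptor genes Rbp3 (4.54 ± 0.69) and Prph2 (4.03 ± 0.69) rose with it. The immunoglobulin joining chain gene Jchain rose from 107 ± 22.7 to 732 ± 193 (log2 2.75 ± 0.25, adjusted p = 1.68e-06), and the semaphorin receptor gene Plxna4 by 2.73 ± 0.75, a call that ended without day 0 replicate 1 (1.85, adjusted p = 0.136), day 4 replicate 2 or day 4 replicate 3. Besides Cxcl2, Fosb and Ptgs2 the largest falls were in Rgs1 (-3.02 ± 0.54), Dnajb13 (-2.45 ± 0.48), Dusp2 (-2.18 ± 0.19), Pxdc1 (-2.11 ± 0.50) and Plk3 (-1.998 ± 0.10), which encode a regulator of G-protein signalling, a cilia-associated chaperone, a MAP kinase phosphatase, a protein of little-known function and a stress-response kinase. The Pxdc1 call ended without day 0 replicate 2 (-1.82, adjusted p = 0.0766), day 4 replicate 1 or day 4 replicate 3.

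Gene lists fixed before the data were examined gave the following at CT26 day 4, with the counts adjusted over the list alone in parentheses. Of 32 type I interferon response genes, 30 rose and 0 fell (30 and 0), median log2 0.76, adjusted p = 1.59e-35 (adjusted p = 0.0684 with an estimated correlation). These included Oasl2 (2.42 ± 0.12), Ifit2 (2.26 ± 0.14), Oas1g (2.15 ± 0.13) and Ifit3 (1.92 ± 0.12). Of 13 MHC class II genes, 0 rose and 10 fell (0 and 10), median log2 -1.46, adjusted p = 1.43e-10 (adjusted p = 0.0684 with an estimated correlation). Among them were H2-Aa (-1.82 ± 0.26), H2-Ob (-1.79 ± 0.26) and Ciita (-1.28 ± 0.20). Of 14 B cell markers, 0 rose and 12 fell (0 and 14), median log2 -1.39, adjusted p = 5.03e-15 (adjusted p = 0.0684 with an estimated correlation). They included Fcer2a (-1.71 ± 0.19) and Fcmr (-1.53 ± 0.19). Of 24 immediate early and stress genes, 0 rose and 12 fell (0 and 14), median log2 -0.35, adjusted p = 5.05e-11 (adjusted p = 0.0684 with an estimated correlation). Of 9 eosinophil markers, 0 rose and 6 fell (0 and 8), median log2 -1.10, adjusted p = 5.14e-09 (adjusted p = 0.0684 with an estimated correlation). Of 81 cytosolic ribosomal protein genes, 0 rose and 49 fell (0 and 63), median log2 -0.41, adjusted p = 1.47e-28 (adjusted p = 0.246 with an estimated correlation). Of 17 secondary granule genes, 8 rose and 1 fell (11 and 1), median log2 0.42, adjusted p = 1.06e-06 (adjusted p = 0.105 with an estimated correlation). Those that rose included Ltf (1.46 ± 0.09), Ngp (1.41 ± 0.08), Camp (1.36 ± 0.12) and Chil3 (1.32 ± 0.16), whose products neutrophils store in their granules.

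Another 7 lists were called at CT26 day 4, again with counts adjusted over the list alone in parentheses. Of 21 mature neutrophil genes, 7 rose and 1 fell (12 and 1), median log2 0.29, adjusted p = 0.000403 (adjusted p = 0.528 with an estimated correlation). Of 20 classical monocyte genes, 4 rose and 0 fell (5 and 2), median log2 0.14, adjusted p = 0.0465 (adjusted p = 0.467 with an estimated correlation). The monocyte list's call ended without day 0 replicate 1 (adjusted p = 0.0915) and without 3 others left out singly. Of 14 MHC class I genes, 6 rose and 0 fell (8 and 0), median log2 0.29, adjusted p = 0.00017 (adjusted p = 0.467 with an estimated correlation). Of 24 NF-kB cytokine and chemokine genes, 4 rose and 9 fell (6 and 12), median log2 -0.40, adjusted p = 0.00955 (adjusted p = 0.0684 with an estimated correlation). Examples include Ccl4 (-1.99 ± 0.30), Ccl3 (-1.60 ± 0.29) and Nfkbiz (-0.90 ± 0.08). Of 25 glycolysis and hypoxia genes, 3 rose and 0 fell (4 and 0), median log2 0.13, adjusted p = 0.0119 (adjusted p = 0.528 with an estimated correlation). The glycolysis call ended without day 0 replicate 3 (adjusted p = 0.0619) or with every library scaled to the same total (median 0.01, adjusted p = 0.138). Of 38 oxidative phosphorylation genes, 0 rose and 1 fell (0 and 0), median log2 -0.18, adjusted p = 0.000202 (adjusted p = 0.528 with an estimated correlation). Of 19 platelet markers, 4 rose and 2 fell (13 and 2), median log2 1.08, adjusted p = 0.00218 (adjusted p = 0.541 with an estimated correlation). The platelet call ended without day 4 replicate 3 (median 0.48, adjusted p = 0.121), its median was 1.89 without day 4 replicate 1, and in edgeR with TMM on 8 CT26 libraries the median was -0.185.

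In lists not called at CT26 day 4, members risen and fallen numbered, with the counts adjusted over the list alone in parentheses, 5 and 1 of 23 (11 and 3) for suppressor cell effector genes and 1 and 2 of 13 (2 and 4) for non-classical monocyte genes. Primary granule and promyelocyte genes gave 1 and 1 of 6 (1 and 1) and NADPH oxidase genes 2 and 2 of 14 (2 and 2). Cell cycle genes gave 1 and 1 of 33 (1 and 0) and unfolded protein response genes 5 and 2 of 24 (5 and 3). G-CSF, GM-CSF and STAT3 signalling genes gave 4 and 3 of 20 (8 and 3) and chemotaxis and adhesion receptor genes 3 and 1 of 22 (6 and 1). Progenitor genes gave 0 and 1 of 9 (0 and 1) and T cell markers 3 and 0 of 15 (4 and 1). NK cell markers gave 0 and 0 of 6 (0 and 0) and erythroid markers 0 and 1 of 7 (1 and 2). Dendritic cell markers gave 0 and 1 of 7 (0 and 1) and melanocyte markers 0 and 0 of 3 (0 and 0). Epithelial markers gave 0 and 1 of 5 (0 and 1). The primary granule genes had a median of 0.06 and a mean of 0.27 while the set test pointed down. In all, limma called 1235 genes at CT26 day 4, 728 higher and 507 lower, of 11373 tested. Without day 4 replicate 1 it called 626, and without day 11 replicate 1, which shares the variance estimate, 2419. With every library scaled to the same total the median shift was -0.12 and the calls were 481 higher and 788 lower.

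By day 8 of CT26 growth Arg1, Nos2 and genes of tissue macrophages, near or at 0 on days 0 and 4, had risen, together with S100a8 and S100a9. Arg1 went from 1.81 ± 2.32 to 441 ± 255 (log2 7.42 ± 0.70, adjusted p = 6.4e-07), a call lost in limma-voom on the recovered reads of 8 CT26 libraries, 2 of them of day 8 (7.55, adjusted p = 0.472). Nos2 reached 87.9 ± 12.3 (log2 5.39 ± 0.52, adjusted p = 7.22e-07). S100a8 reached 131700 ± 13980 (log2 0.80 ± 0.18, adjusted p = 0.00254) and S100a9 322500 ± 35040 (log2 0.68 ± 0.20, adjusted p = 0.0162), and the S100a9 call ended without day 0 replicate 3 (0.55, adjusted p = 0.116), day 0 replicate 2, day 8 replicate 2 or day 8 replicate 3. The complement gene C1qa (chromosome 4, 136895917 to 136898803, minus strand) was listed at 0 in the day 0 and day 4 libraries and stood at 183 ± 69.0.

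Other large rises at CT26 day 8 were in the endothelial lipase gene Lipg, from 3.07 ± 2.07 to 473 ± 142 (log2 6.93 ± 0.29, adjusted p = 4.81e-11), and the acute-phase gene Saa3, from 1.26 ± 0.631 to 208 ± 105 (log2 6.40 ± 0.57, adjusted p = 2.86e-07). The macrophage-expressed genes C1qc (6.63 ± 0.57), Fcna (6.58 ± 0.61), Cd5l (6.29 ± 0.73) and Prg4 (6.91 ± 0.58) rose with them. Of 13 tissue macrophage genes collected after the values had been seen, 0 rose at day 4, 11 rose at day 8 and 13 rose at day 11, and none fell. Bpifa6, of the BPI-fold family, fell from 62.6 ± 3.38 and Psapl1, related to prosaposin, from 13.6 ± 3.23, and both were listed at 0 at day 8. The pre-B cell gene Vpreb3 fell from 24.8 ± 1.56 to 1.68 ± 1.53 (log2 -3.48 ± 0.59, adjusted p = 0.000259), followed by Enkur (-2.85 ± 0.62), Fosb (-2.72 ± 0.11), Dusp2 (-2.59 ± 0.19), Mir27a (-2.40 ± 0.47) and Snora78 (-2.26 ± 0.48), the last 2 being genes of small RNAs, which poly-A libraries capture irregularly.

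Granule, neutrophil, glycolysis and interferon lists were among those called higher at CT26 day 8 (counts in parentheses are adjusted over the list alone). Of 17 secondary granule genes, 12 rose and 1 fell (12 and 2), median log2 0.88, adjusted p = 2.38e-08 (adjusted p = 0.181 with an estimated correlation). Examples were Olfm4 (1.92 ± 0.11), Ngp (1.46 ± 0.08) and Lcn2 (1.21 ± 0.11). Of 21 mature neutrophil genes, 15 rose and 0 fell (15 and 0), median log2 0.66, adjusted p = 1.3e-08 (adjusted p = 0.279 with an estimated correlation). These included Stfa3 (1.79 ± 0.19), Steap4 (1.56 ± 0.12) and Il1r2 (1.10 ± 0.07). Of 25 glycolysis and hypoxia genes, 19 rose and 2 fell (21 and 2), median log2 0.64, adjusted p = 2.52e-10 (adjusted p = 0.181 with an estimated correlation). The phosphofructokinase gene Pfkl went from 238 ± 6.23 to 638 ± 56.9 (log2 1.41 ± 0.09, adjusted p = 7.28e-09). Of 23 suppressor cell effector genes, 14 rose and 4 fell (14 and 5), median log2 0.56, adjusted p = 0.000321 (adjusted p = 0.189 with an estimated correlation). Wfdc17 went from 1702 ± 123 to 12030 ± 1345, and Il4ra (1.72 ± 0.10) and Hif1a (1.51 ± 0.10) rose. Of 20 G-CSF, GM-CSF and STAT3 signalling genes, 13 rose and 0 fell (13 and 0), median log2 0.38, adjusted p = 2.32e-05 (adjusted p = 0.321 with an estimated correlation). Of 32 type I interferon response genes, 26 rose and 0 fell (28 and 0), median log2 0.73, adjusted p = 1.01e-16 (adjusted p = 0.181 with an estimated correlation). They included Zbp1 (2.50 ± 0.15), Oasl2 (2.20 ± 0.12) and Stat2 (1.65 ± 0.13). Of 14 MHC class I genes, 8 rose and 0 fell (10 and 0), median log2 0.29, adjusted p = 5.46e-05 (adjusted p = 0.321 with an estimated correlation). Of 20 classical monocyte genes, 7 rose and 2 fell (7 and 2), median log2 0.30, adjusted p = 0.0361 (adjusted p = 0.321 with an estimated correlation). The classical monocyte call ended without day 0 replicate 1 (adjusted p = 0.0766) or day 8 replicate 2, and with every library scaled to the same total.

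Cell cycle genes were also called higher at CT26 day 8 (parentheses hold counts adjusted over the list alone). Of 33, 6 rose and 1 fell (4 and 1), median log2 0.67, adjusted p = 0.00604 (adjusted p = 0.455 with an estimated correlation). These included Ccna2 (3.64 ± 0.62), Top2a (1.71 ± 0.43) and Mcm4 (0.77 ± 0.10). Falls were called in 6 lists. Of 9 eosinophil markers, 0 rose and 9 fell (0 and 9), median log2 -1.46, adjusted p = 1.38e-07 (adjusted p = 0.181 with an estimated correlation). Among them were Il5ra (-1.63 ± 0.14) and Ccr3 (-1.44 ± 0.14). Of 14 B cell markers, 0 rose and 10 fell (0 and 12), median log2 -0.88, adjusted p = 1.39e-06 (adjusted p = 0.216 with an estimated correlation). Of 13 non-classical monocyte genes, 2 rose and 6 fell (2 and 8), median log2 -0.69, adjusted p = 0.00392 (adjusted p = 0.181 with an estimated correlation). Members included Nr4a1 (-2.06 ± 0.08), Ace (-1.41 ± 0.27) and Spn (-0.87 ± 0.12). Of 24 immediate early and stress genes, 4 rose and 12 fell (4 and 12), median log2 -0.26, adjusted p = 3.72e-05 (adjusted p = 0.279 with an estimated correlation). Of 13 MHC class II genes, 0 rose and 3 fell (0 and 3), median log2 -0.39, adjusted p = 0.00626 (adjusted p = 0.356 with an estimated correlation). H2-Aa was not called (log2 -0.63 ± 0.26, adjusted p = 0.0856). Of 81 cytosolic ribosomal protein genes, 0 rose and 27 fell (0 and 36), median log2 -0.26, adjusted p = 1.38e-07 (adjusted p = 0.455 with an estimated correlation). The ribosomal median was -0.173 without day 0 replicate 1. The MHC class II call ended with every library scaled to the same total (adjusted p = 0.0505).

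Members risen and fallen in lists not called at CT26 day 8, with the counts adjusted over the list alone in parentheses, were 3 and 2 of 6 (3 and 2) for primary granule and promyelocyte genes and 6 and 3 of 14 (7 and 3) for NADPH oxidase genes. NF-kB cytokine and chemokine genes gave 6 and 10 of 24 (6 and 11) and oxidative phosphorylation genes 1 and 6 of 38 (1 and 4). Unfolded protein response genes gave 2 and 2 of 24 (2 and 2) and chemotaxis and adhesion receptor genes 10 and 4 of 22 (10 and 4). Progenitor genes gave 1 and 1 of 9 (1 and 1) with Kit (2.35 ± 0.32) and T cell markers 2 and 1 of 15 (2 and 1). NK cell markers gave 1 and 0 of 6 (1 and 0) and erythroid markers 0 and 1 of 7 (0 and 1). Platelet markers gave 0 and 2 of 19 (0 and 2) and dendritic cell markers 2 and 3 of 7 (2 and 3). Melanocyte markers gave 0 and 1 of 3 (0 and 1) and epithelial markers 1 and 1 of 5 (2 and 1). The dendritic cell markers had a median of 0.17 and a mean of -0.20, and their set test pointed down. At day 8, 3056 genes were called, 1712 higher and 1344 lower. Under total scaling the median shift was -0.17 and 1163 were higher and 2771 lower.

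At day 11 of CT26 growth Arg1, Nos2 and the macrophage genes were again higher than at day 0, and Egr1, Fosb, Ear1 and Ptgs2 were among the largest falls. Arg1 reached 2394 ± 2599 (log2 9.48 ± 0.70, adjusted p = 9.13e-09), with 5379 in replicate 1 against 628 and 1175 in the other 2, and the log2 fold change without replicate 1 was 8.60. In limma-voom on the recovered reads the Arg1 call was lost (9.96, adjusted p = 0.228). Nos2 reached 443 ± 57.6 (log2 7.71 ± 0.52, adjusted p = 2.81e-09), S100a8 151700 ± 29930 (log2 0.99 ± 0.18, adjusted p = 0.000174) and S100a9 369600 ± 31610 (log2 0.88 ± 0.20, adjusted p = 0.00138). Egr1, an immediate early transcription factor gene (chromosome 18, 34859823 to 34864984, plus strand), fell from 21120 ± 2579 to 327 ± 74.1 (log2 -6.03 ± 0.14, adjusted p = 7.73e-15). Fosb fell to 43.2 ± 7.39 (log2 -5.99 ± 0.11, adjusted p = 6.74e-16) and Ptgs2 to 54.4 ± 5.79 (log2 -5.70 ± 0.12, adjusted p = 2.76e-15). The eosinophil ribonuclease gene Ear1 fell from 535 ± 48.3 to 8.21 ± 2.54 (log2 -5.90 ± 0.17, adjusted p = 1.03e-13).

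**Figure D1:**
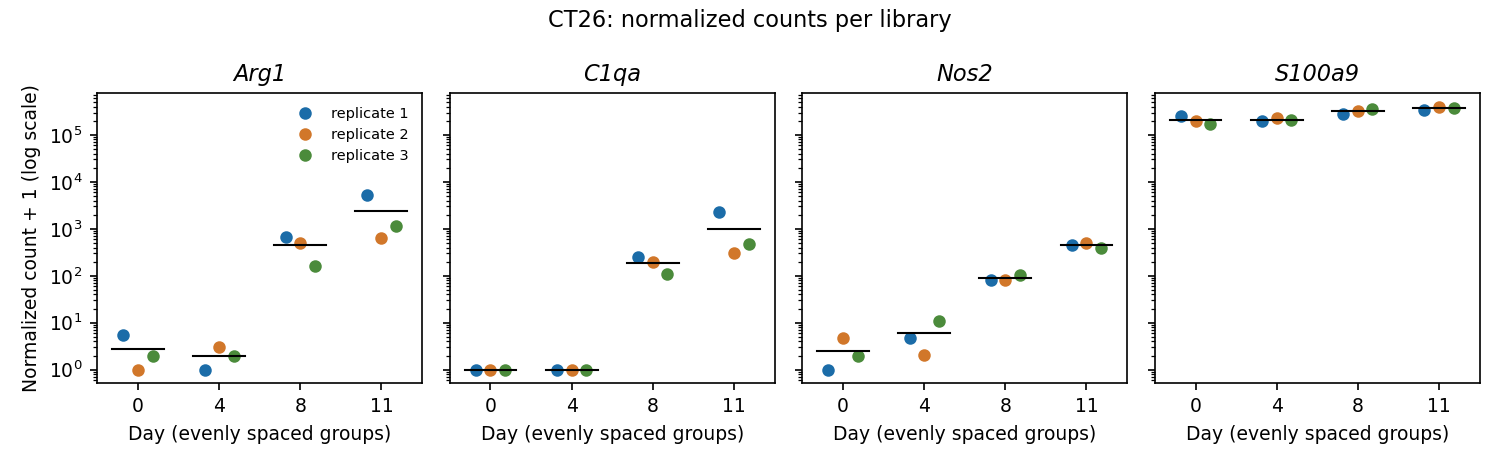
Normalized count plus 1 on a log scale for Arg1, C1qa, Nos2 and S100a9 in the 12 CT26 libraries, grouped by day 0, 4, 8 and 11 at even spacing, with 1 point per library coloured by replicate number and a black line at each mean. C1qa is listed at 0 on days 0 and 4, Arg1 in day 11 replicate 1 stands at 5379, and S100a9 moves least of the 4 genes.

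For lists in this paragraph, counts in parentheses are adjusted over the list alone. Among the largest rises at CT26 day 11, C1qa stood at 1005 ± 1071, Saa3 at 1087 ± 1067 (log2 8.49 ± 0.57, adjusted p = 2.73e-09) and Lipg at 860.3 ± 246 (log2 7.80 ± 0.29, adjusted p = 1.6e-12), and Fcna (8.75 ± 0.61), C1qc (8.56 ± 0.57), Cd5l (8.18 ± 0.73) and C1qb (8.06 ± 0.58) rose as well. Without day 11 replicate 1 Saa3 was at 7.71, Fcna at 7.85, C1qc at 7.72, Cd5l at 7.21 and C1qb at 7.24. That library held 12260 summed counts of macrophage genes, against 1515 and 2681 in the others of day 11 and 584.6 to 1785 at day 8. Il4, a cytokine gene of basophils, eosinophils and T cells, fell from 70.5 ± 9.51 to 1.07 ± 1.16 (log2 -5.27 ± 0.37, adjusted p = 4.82e-09), with Ear2 (-5.37 ± 0.43) and Alox12e (-5.34 ± 0.40) falling too and Bpifa6 listed at 0. Of 9 eosinophil markers, 0 rose and 9 fell (0 and 9), median log2 -3.93, adjusted p = 4.97e-10 (adjusted p = 0.118 with an estimated correlation). Ccr3, the eotaxin receptor gene, went from 2919 ± 111 to 222 ± 58.4. Of 25 glycolysis and hypoxia genes, 22 rose and 1 fell (23 and 1), median log2 1.37, adjusted p = 1.77e-13 (adjusted p = 0.118 with an estimated correlation). Pfkl reached 1649 ± 154 (log2 2.78 ± 0.09, adjusted p = 4e-13), and Egln3 (2.29 ± 0.09), Tpi1 (2.01 ± 0.10), Pgam1 (1.88 ± 0.09) and Ldha (1.46 ± 0.08) rose with it. Of 17 secondary granule genes, 15 rose and 1 fell (15 and 1), median log2 1.72, adjusted p = 8.76e-10 (adjusted p = 0.118 with an estimated correlation). Ngp stood at 12370 ± 1337, and Chil3 (3.20 ± 0.16) and Ltf (2.41 ± 0.09) rose. Of 21 mature neutrophil genes, 18 rose and 0 fell (18 and 0), median log2 0.93, adjusted p = 8.76e-10 (adjusted p = 0.248 with an estimated correlation). Stfa2 went from 468 ± 44.1 to 3800 ± 491.

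Suppressor cell effector genes moved in both directions at CT26 day 11 (counts in parentheses adjusted over the list alone). Of 23, 15 rose and 6 fell (15 and 6), median log2 0.82, adjusted p = 0.00406 (adjusted p = 0.248 with an estimated correlation). Examples were Wfdc17 (3.31 ± 0.13), Mif (3.31 ± 0.19) and Il4ra (2.27 ± 0.10) among the risen and Ptgs2 among the fallen. Of 14 NADPH oxidase genes, 8 rose and 2 fell (8 and 2), median log2 0.42, adjusted p = 0.0166 (adjusted p = 0.255 with an estimated correlation). Examples were Nfe2l2 (1.58 ± 0.09) and Ncf4 (1.05 ± 0.08) and, in the other direction, the catalase gene Cat (-3.23 ± 0.20). Of 20 G-CSF, GM-CSF and STAT3 signalling genes, 12 rose and 3 fell (12 and 4), median log2 0.54, adjusted p = 0.00667 (adjusted p = 0.487 with an estimated correlation). Of 33 cell cycle genes, 16 rose and 1 fell (16 and 1), median log2 0.84, adjusted p = 0.00246 (adjusted p = 0.487 with an estimated correlation). They included Ccna2 (3.68 ± 0.62) and Ccnb2 (2.04 ± 0.37). The cell cycle call ended without day 11 replicate 1 (adjusted p = 0.0621). Of 14 MHC class I genes, 6 rose and 0 fell (6 and 0), median log2 0.25, adjusted p = 0.0246 (adjusted p = 0.54 with an estimated correlation). The MHC class I call ended under total scaling (median -0.04, adjusted p = 0.198), without day 0 replicate 3 and without day 11 replicate 2.

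Lymphocyte, MHC class II and non-classical monocyte lists were among those called lower at CT26 day 11 (in parentheses, counts adjusted over the list alone). Of 14 B cell markers, 0 rose and 14 fell (0 and 14), median log2 -2.52, adjusted p = 3.05e-10 (adjusted p = 0.125 with an estimated correlation). Examples include Fcer2a (-3.62 ± 0.19) and Bank1 (-2.84 ± 0.15). Of 13 MHC class II genes, 0 rose and 12 fell (0 and 12), median log2 -2.01, adjusted p = 4.5e-07 (adjusted p = 0.154 with an estimated correlation). Examples were Ciita (-2.46 ± 0.20), H2-Aa (-2.27 ± 0.26) and H2-Ab1 (-2.16 ± 0.24). Of 13 non-classical monocyte genes, 1 rose and 7 fell (1 and 8), median log2 -0.70, adjusted p = 0.00246 (adjusted p = 0.143 with an estimated correlation). These included Ace (-4.83 ± 0.27), Adgre4 (-4.45 ± 0.32) and Nr4a1 (-3.22 ± 0.08). Of 15 T cell markers, 0 rose and 5 fell (0 and 3), median log2 -0.99, adjusted p = 0.0209 (adjusted p = 0.248 with an estimated correlation). Among them were Cd3g (-3.18 ± 0.46) and Lck (-1.39 ± 0.40, or -0.914 without day 11 replicate 1). Of 6 NK cell markers, 0 rose and 3 fell (0 and 3), median log2 -1.14, adjusted p = 0.0418 (adjusted p = 0.255 with an estimated correlation). They included Gzma (-2.71 ± 0.36) and Ncr1 (-2.42 ± 0.52). The T cell and NK cell calls both ended under total scaling (adjusted p = 0.189 and adjusted p = 0.191), and the NK cell call ended without each of 4 libraries left out singly, with adjusted p = 0.0707 without day 11 replicate 3. Of 24 immediate early and stress genes, 6 rose and 15 fell (6 and 15), median log2 -0.64, adjusted p = 0.000834 (adjusted p = 0.274 with an estimated correlation). Of 24 NF-kB cytokine and chemokine genes, 5 rose and 13 fell (5 and 14), median log2 -0.48, adjusted p = 0.0451 (adjusted p = 0.162 with an estimated correlation). Examples were Tnf (-1.21 ± 0.12) and Nfkbiz (-0.93 ± 0.08) and, rising, Birc3 (1.08 ± 0.08). This NF-kB call ended without day 0 replicate 1 (adjusted p = 0.0629) or day 11 replicate 3. Of 81 cytosolic ribosomal protein genes, 2 rose and 48 fell (2 and 49), median log2 -0.34, adjusted p = 1.17e-06 (adjusted p = 0.54 with an estimated correlation).

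Type I interferon response genes were not called as a list at CT26 day 11, with 13 and 6 of 32 (14 and 7) risen and fallen, a median of 0.22 and adjusted p = 0.0542. Oasl2 (1.79 ± 0.12) and Zbp1 (2.01 ± 0.15) rose and Ifit2 (-0.58 ± 0.14) fell. Risen and fallen members of the other lists not called, with the counts adjusted over the list alone in parentheses, were 5 and 6 of 20 (6 and 6) for classical monocyte genes and 3 and 2 of 6 (3 and 2) for primary granule and promyelocyte genes. Oxidative phosphorylation genes gave 6 and 9 of 38 (5 and 6) and unfolded protein response genes 5 and 2 of 24 (3 and 2). Chemotaxis and adhesion receptor genes gave 10 and 6 of 22 (10 and 6) around a median of 0.09 and a mean of -0.13. Progenitor genes gave 2 and 3 of 9 (2 and 3), with Kit (4.18 ± 0.32). Erythroid markers gave 2 and 2 of 7 (2 and 3) and platelet markers 1 and 6 of 19 (1 and 5). Dendritic cell markers gave 2 and 4 of 7 (2 and 4) with Itgax (-1.61 ± 0.08) and melanocyte markers 0 and 1 of 3 (0 and 1). Epithelial markers gave 3 and 1 of 5 (3 and 1). In total 5721 genes were called, 2990 higher and 2731 lower. Under total scaling the median shift was -0.28 and 1716 were higher and 4631 lower, and with upper quartile scaling 2815 and 2906.

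Between successive days of CT26 growth, Pard3 and Mx2 fell back at day 8 and Arg1 rose. From day 4 to day 8 Arg1 rose (log2 7.70 ± 0.70, adjusted p = 1.09e-06), Nos2 rose (log2 4.22 ± 0.52, adjusted p = 2.64e-05) and Pfkl rose (log2 1.28 ± 0.09, adjusted p = 1e-07), while Pard3 (-5.97 ± 0.77), Mx2 (-2.31 ± 0.26) and Jchain (-1.54 ± 0.25) fell and H2-Aa rose (log2 1.18 ± 0.26, adjusted p = 0.0053). From day 8 to day 11 Arg1 was just called (log2 2.07 ± 0.70, adjusted p = 0.0466), a call that ended without day 11 replicate 1 (1.19, adjusted p = 0.156), day 8 replicate 3 (1.46, adjusted p = 0.207), day 8 replicate 2, day 11 replicate 3, day 0 replicate 3, day 4 replicate 2 or day 4 replicate 3. Rises were called in Nos2 (log2 2.32 ± 0.52, adjusted p = 0.00418), Pfkl (log2 1.37 ± 0.09, adjusted p = 2.65e-08) and Ngp (log2 1.17 ± 0.08, adjusted p = 6.92e-08). Ear1 fell (log2 -4.36 ± 0.17, adjusted p = 2.55e-11), Egr1 fell (log2 -4.14 ± 0.14, adjusted p = 4.79e-12) and so did Fosb (-3.27 ± 0.11), Jchain (-3.89 ± 0.25) and Ifit2 (-1.64 ± 0.14). Egr1 was not called between days 4 and 8 (log2 0.09 ± 0.14, adjusted p = 0.76). The 2 steps gave 1522 called genes (844 higher, 678 lower) and 2375 (1244 higher, 1131 lower). With total scaling they gave 782 higher and 1162 lower, and 821 higher and 1688 lower around a median shift of -0.11, and with upper quartile scaling the second gave 1084 and 1241. Without CT26 day 11 replicate 1 the second step gave 3428 and without day 8 replicate 1 it gave 1583. Over all days 5661 CT26 genes were called.

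At day 4 of B16 growth Tubb1 and Alas2 rose and Lars2 and Rn45s fell. Tubb1, the platelet tubulin gene (chromosome 2, 174450695 to 174457882, plus strand), went from 259 ± 194 to 7114 ± 5252 (log2 4.82 ± 0.55, adjusted p = 5.09e-05). Alas2, a haem synthesis gene of red cell precursors, went from 49.4 ± 14.7 to 621 ± 38.9 (log2 3.67 ± 0.29, adjusted p = 5.08e-06). Lars2, a mitochondrial leucyl-tRNA synthetase gene, fell from 55220 ± 5200 to 7107 ± 428 (log2 -2.96 ± 0.13, adjusted p = 1.83e-07), and Rn45s, with which Lars2 moved on all B16 days, from 376900 ± 44410 to 71160 ± 5453 (log2 -2.40 ± 0.13, adjusted p = 6.63e-07). S100a8 (log2 -0.03 ± 0.09, adjusted p = 0.852) and S100a9 (log2 -0.06 ± 0.08, adjusted p = 0.599) were not called. Nos2 went from 6.22 ± 7.10 to 38.9 ± 21.6 (log2 2.83 ± 0.82, adjusted p = 0.0174), a call that ended without day 0 replicate 1 (adjusted p = 0.0607) or day 4 replicate 1 (adjusted p = 0.152). Arg1 was too low to test in B16, with a mean of 1.54 and at most 4.1 in any library.

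The largest B16 day 4 rises were in Mobp (5.72 ± 1.01), Apcdd1 (5.24 ± 0.60), Serpinb2 (4.81 ± 0.64), Mest (4.66 ± 0.56), Unc13c (4.63 ± 1.01), Afap1l1 (4.61 ± 0.78) and Aldh1a1 (4.53 ± 0.63), which encode a myelin protein, a Wnt inhibitor, a plasminogen activator inhibitor, an imprinted hydrolase, a synaptic protein, an actin-binding protein and a retinal dehydrogenase. The 2 day 4 libraries lay far apart, with Mobp at 137 ± 155 and Unc13c at 107 ± 127. The largest falls besides Lars2 were in Kcna2 (-3.47 ± 0.74, or -2.145 without day 4 replicate 1), Gucy1a2 (-3.15 ± 0.58), Prune2 (-3.02 ± 0.81), Tbx18 (-3.003 ± 0.84), Mir6236 (-2.73 ± 0.14), Atp1b4 (-2.58 ± 0.74) and Abhd12b (-2.54 ± 0.66), which include genes of a potassium channel, a guanylate cyclase subunit and a T-box factor. With 2 libraries at day 4, the Abhd12b and Prune2 calls ended without day 4 replicate 1 (adjusted p = 0.0623 and adjusted p = 0.0736) and the Atp1b4 and Tbx18 calls without day 4 replicate 3 (adjusted p = 0.132 and adjusted p = 0.151). The gene count at B16 day 4 was 4276 (2425 higher, 1851 lower) of 11930 tested and 2782 without day 4 replicate 1. With upper quartile scaling 1946 were higher and 2434 lower.

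Of the lists called at B16 day 4, platelet markers moved furthest by median (counts in parentheses are adjusted over the list alone). Of 19 platelet markers, 19 rose and 0 fell (19 and 0), median log2 3.60, adjusted p = 7.79e-11 (adjusted p = 0.405 with an estimated correlation). Pf4 went from 688 ± 618 to 6954 ± 4584 and Vwf from 177 ± 137 to 3278 ± 2192. Of 81 cytosolic ribosomal protein genes, 0 rose and 76 fell (0 and 77), median log2 -0.94, adjusted p = 6.38e-43 (adjusted p = 0.223 with an estimated correlation). Rps3a1 went from 7925 ± 128 to 3077 ± 148. Of 32 type I interferon response genes, 24 rose and 0 fell (26 and 0), median log2 0.81, adjusted p = 6.26e-10 (adjusted p = 0.463 with an estimated correlation). Slfn4 went from 30480 ± 5060 to 84310 ± 902, and Ifih1 (1.30 ± 0.16), Oasl1 (0.96 ± 0.10) and Oasl2 (0.53 ± 0.13) rose. Of 21 mature neutrophil genes, 12 rose and 2 fell (13 and 2), median log2 0.32, adjusted p = 0.000991 (adjusted p = 0.187 with an estimated correlation). Examples were Steap4 (1.54 ± 0.14), Mmp25 (1.47 ± 0.14) and Fpr1 (0.85 ± 0.05). Of 22 suppressor cell effector genes, 13 rose and 4 fell (14 and 4), median log2 0.41, adjusted p = 0.00939 (adjusted p = 0.223 with an estimated correlation). These included Hif1a (1.22 ± 0.09), Il4ra (0.88 ± 0.10) and Arg2 (0.74 ± 0.06). Of 22 chemotaxis and adhesion receptor genes, 14 rose and 2 fell (14 and 2), median log2 0.44, adjusted p = 0.000144 (adjusted p = 0.187 with an estimated correlation). Of 20 G-CSF, GM-CSF and STAT3 signalling genes, 7 rose and 0 fell (10 and 1), median log2 0.17, adjusted p = 0.0295 (adjusted p = 0.463 with an estimated correlation). The G-CSF list's median was 0.264 without day 4 replicate 1, and its call ended without day 0 replicate 1 (adjusted p = 0.072) and with upper quartile scaling (adjusted p = 0.0878).

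Erythroid markers were called higher at B16 day 4 (in parentheses, counts adjusted over the list alone). Of 8, 6 rose and 1 fell (6 and 1), median log2 1.11, adjusted p = 0.0295 (adjusted p = 0.223 with an estimated correlation). Members included Hbb-bs (2.78 ± 0.56) and Bpgm (1.62 ± 0.18). The erythroid call ended without day 4 replicate 3 (median 0.57, adjusted p = 0.0891). Of 24 immediate early and stress genes, 5 rose and 11 fell (5 and 11), median log2 -0.27, adjusted p = 0.00819 (adjusted p = 0.407 with an estimated correlation). Without day 4 replicate 1 the median was -0.0898. Examples were Ppp1r15a (-1.49 ± 0.08), Fosb (-1.27 ± 0.13) and Zfp36 (-0.90 ± 0.06). Of 38 oxidative phosphorylation genes, 3 rose and 20 fell (4 and 22), median log2 -0.33, adjusted p = 0.000144 (adjusted p = 0.57 with an estimated correlation). Lists not called gave, as members risen and fallen, 2 and 1 of 6 (2 and 1) for primary granule and promyelocyte genes and 6 and 3 of 18 (6 and 3) for secondary granule genes. Classical monocyte genes gave 6 and 1 of 20 (6 and 1) and non-classical monocyte genes 3 and 6 of 14 (4 and 8). NADPH oxidase genes gave 6 and 5 of 14 (6 and 5) around a median of -0.12 and a mean of 0.24. MHC class II genes gave 0 and 5 of 13 (0 and 5) and MHC class I genes 2 and 2 of 14 (2 and 2). Cell cycle genes gave 2 and 3 of 32 (2 and 3) and NF-kB cytokine and chemokine genes 5 and 6 of 23 (5 and 6). Glycolysis and hypoxia genes gave 8 and 2 of 25 (8 and 2) and unfolded protein response genes 6 and 5 of 24 (6 and 5). Progenitor genes gave 3 and 1 of 11 (3 and 1) and B cell markers 1 and 5 of 14 (1 and 5). T cell markers gave 1 and 2 of 17 (1 and 2) and NK cell markers 0 and 0 of 9 (0 and 0). Eosinophil markers gave 1 and 1 of 6 (1 and 1) and dendritic cell markers 1 and 1 of 9 (0 and 1). Melanocyte markers gave 0 and 3 of 4 (0 and 3) and epithelial markers 0 and 0 of 4 (0 and 0).

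At B16 day 8 Alox15 and Ccr3 rose and H2-D1 and S100a9 fell. Alox15, a lipoxygenase gene of eosinophils, went from 21.2 ± 1.78 to 688 ± 76.5 (log2 4.95 ± 0.23, adjusted p = 3.51e-08), and Ccr3 from 70.3 ± 12.8 to 778 ± 71.0 (log2 3.46 ± 0.15, adjusted p = 2.65e-08). The MHC class I gene H2-D1 fell from 74440 ± 7156 to 37510 ± 2198 (log2 -0.99 ± 0.07, adjusted p = 4.01e-07). S100a9 fell from 309600 ± 8669 to 216400 ± 19770 (log2 -0.52 ± 0.07, adjusted p = 4.47e-05), while S100a8 (log2 -0.04 ± 0.08, adjusted p = 0.685) and Nos2 (log2 -1.28 ± 0.73, adjusted p = 0.158) were not called. Map3k6, a kinase gene, was listed at 0 at day 0 and stood at 45.4 ± 9.04. Itga2, a collagen receptor subunit gene of platelets, went from 1.90 ± 0.772 to 113 ± 23.1 (log2 5.31 ± 0.48, adjusted p = 2.08e-06), and Hist1h4m (5.15 ± 0.43), P2ry14 (5.12 ± 0.62), Apcdd1 (5.05 ± 0.54), Serpinb2 (4.67 ± 0.57) and Fgfr1 (4.66 ± 0.59) rose too. The homeobox gene Rhox8 fell from 412 ± 161 to 22.8 ± 5.10 (log2 -4.07 ± 0.25, adjusted p = 1.49e-07) and the Wnt ligand gene Wnt4 from 169.6 ± 6.13 to 14.3 ± 5.88 (log2 -3.57 ± 0.27, adjusted p = 5.33e-07), with Prune2 (-3.92 ± 0.72), Tbx18 (-3.64 ± 0.75), Phex (-3.62 ± 0.26), Abhd12b (-3.61 ± 0.59), Mcc (-3.61 ± 0.47) and Itgb6 (-3.54 ± 0.39) falling as well.

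Rn45s took 2.57% to 3.1% of the day 0 libraries and 0.427% to 0.522% of those of day 8. Lists called at B16 day 8 follow, with counts adjusted over the list alone in parentheses. Of 19 platelet markers, 19 rose and 0 fell (19 and 0), median log2 3.38, adjusted p = 2.33e-07 (adjusted p = 0.692 with an estimated correlation). Tubb1 stood at 4867 ± 1541, and Gp6 (4.29 ± 0.49), Vwf (4.14 ± 0.46), Ppbp (3.40 ± 0.50) and F5 (2.77 ± 0.24) rose. Of 6 eosinophil markers, 5 rose and 0 fell (5 and 0), median log2 2.57, adjusted p = 0.00478 (adjusted p = 0.293 with an estimated correlation). Among them were Ear1 (3.83 ± 0.49), Il5ra (1.67 ± 0.23) and Siglecf (1.38 ± 0.10). Of 22 chemotaxis and adhesion receptor genes, 14 rose and 4 fell (14 and 4), median log2 0.40, adjusted p = 0.0243 (adjusted p = 0.594 with an estimated correlation). Of 81 cytosolic ribosomal protein genes, 0 rose and 75 fell (0 and 76), median log2 -0.86, adjusted p = 4.06e-23 (adjusted p = 0.594 with an estimated correlation). Of 38 oxidative phosphorylation genes, 3 rose and 25 fell (3 and 25), median log2 -0.49, adjusted p = 8.84e-05 (adjusted p = 0.692 with an estimated correlation). Of 14 MHC class I genes, 2 rose and 11 fell (2 and 11), median log2 -0.86, adjusted p = 0.00727 (adjusted p = 0.713 with an estimated correlation). Of 13 MHC class II genes, 1 rose and 9 fell (1 and 10), median log2 -0.88, adjusted p = 0.0105 (adjusted p = 0.692 with an estimated correlation). These included H2-Eb1 (-1.31 ± 0.14), H2-Ab1 (-1.25 ± 0.13) and Cd74 (-1.004 ± 0.13). Of 14 B cell markers, 1 rose and 9 fell (1 and 9), median log2 -1.05, adjusted p = 0.00658 (adjusted p = 0.7 with an estimated correlation). Of 25 glycolysis and hypoxia genes, 5 rose and 14 fell (5 and 14), median log2 -0.27, adjusted p = 0.0343 (adjusted p = 0.483 with an estimated correlation). Examples were Ldha (-1.02 ± 0.07) and Slc16a3 (-0.74 ± 0.06) falling and Eno1 (1.96 ± 0.11) rising. This glycolysis call ended under total scaling (median -0.14, adjusted p = 0.129).

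Type I interferon response genes were not called as a list at B16 day 8, with 3 and 16 of 32 (3 and 18) risen and fallen (in parentheses adjusted over the list alone), a median of -0.36 and adjusted p = 0.0732. Among them Oas1g (-1.42 ± 0.18), Bst2 (-1.38 ± 0.19) and Rsad2 (-0.84 ± 0.11) fell and Ifih1 (1.05 ± 0.14) rose. NADPH oxidase genes gave 1 and 8 of 14 (1 and 8) with adjusted p = 0.0557, and immediate early and stress genes 6 and 12 of 24 (6 and 13) with adjusted p = 0.0841. Primary granule and promyelocyte genes gave 1 and 3 of 6 (1 and 3) and secondary granule genes 10 and 5 of 18 (11 and 5). Mature neutrophil genes gave 6 and 11 of 21 (6 and 11), with Mmp25 (1.62 ± 0.12) and Retnlg (-1.24 ± 0.09). Classical monocyte genes gave 5 and 9 of 20 (5 and 10) and non-classical monocyte genes 4 and 5 of 14 (4 and 5). Suppressor cell effector genes gave 9 and 4 of 22 (9 and 4) and cell cycle genes 4 and 2 of 32 (3 and 2). NF-kB cytokine and chemokine genes gave 5 and 7 of 23 (5 and 7) and unfolded protein response genes 5 and 12 of 24 (5 and 12). G-CSF, GM-CSF and STAT3 signalling genes gave 8 and 9 of 20 (8 and 9). Progenitor genes gave 2 and 1 of 11 (2 and 1) and T cell markers 3 and 2 of 17 (3 and 2). NK cell markers gave 1 and 0 of 9 (0 and 0) and erythroid markers 2 and 4 of 8 (2 and 4). Dendritic cell markers gave 1 and 1 of 9 (1 and 1) and melanocyte markers 0 and 1 of 4 (0 and 1). Epithelial markers gave 0 and 1 of 4 (0 and 1). The 6676 genes called divided into 3415 higher and 3261 lower, and under total scaling, with a median shift of 0.12, into 4087 and 2587. Upper quartile scaling shifted the median by -0.12 and gave 2830 higher and 3911 lower.

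At B16 day 11 Egr1, S100a8 and S100a9 rose and 23 of 23 photoreceptor genes fell. Egr1 went from 137 ± 19.2 to 1942 ± 91.2 (log2 3.83 ± 0.18, adjusted p = 1.64e-07). S100a8 reached 174600 ± 12150 (log2 0.62 ± 0.08, adjusted p = 7.09e-05) and S100a9 370900 ± 19460 (log2 0.26 ± 0.07, adjusted p = 0.00887), the latter not called under total scaling (0.12, adjusted p = 0.163). Nos2 stood at 22.1 ± 5.74 (log2 2.12 ± 0.73, adjusted p = 0.032), a call that ended without each of 5 libraries in turn, with adjusted p = 0.13 without day 0 replicate 1. The rod phosphodiesterase gene Pde6g fell from 565 ± 179 to 4.89 ± 3.21 (log2 -6.74 ± 0.71, adjusted p = 1.64e-05). The photoreceptor genes Rcvrn, at 248 ± 64.5 on day 0, and Opn1sw, at 209.9 ± 52.1, were listed at 0 on day 11, as was Mgarp, a mitochondrial protein gene, from 83.0 ± 28.6. The other large falls, Guca1b (-7.02 ± 0.73), Nrl (-6.74 ± 0.74), Cnga1 (-6.49 ± 0.77) and Gngt1 (-6.48 ± 0.72), were also in photoreceptor genes. Besides Egr1 the largest rises were in Apcdd1 (4.13 ± 0.54), Itga2 (3.65 ± 0.48), Mest (3.62 ± 0.50), Hist1h4m (3.58 ± 0.43), Afap1l1 (3.53 ± 0.70), Tubb1 (3.44 ± 0.49) and Prokr1 (3.36 ± 0.49).

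**Figure D2:**
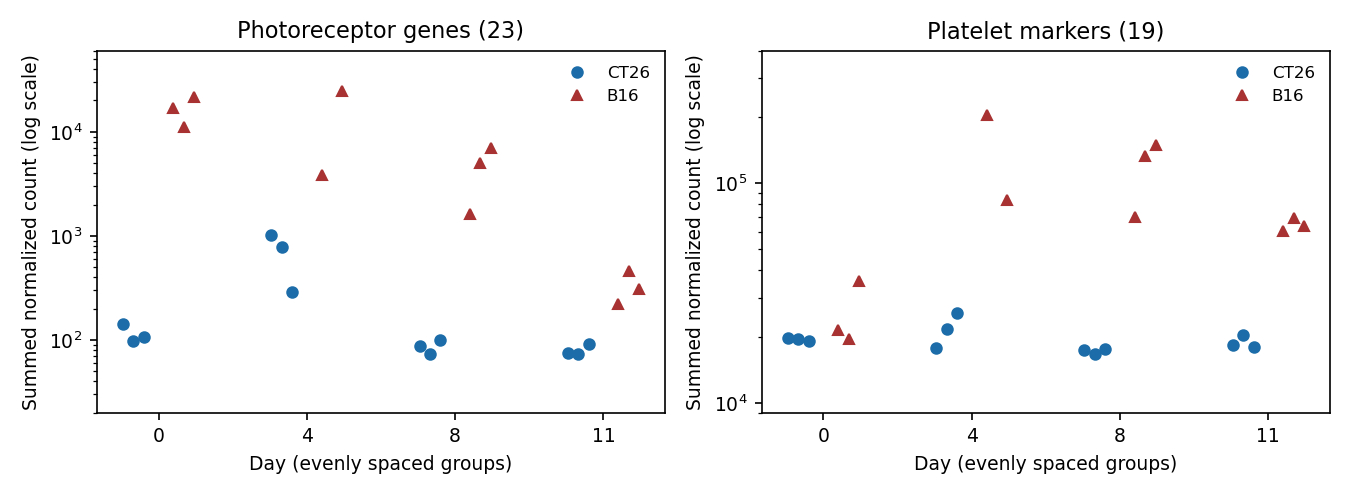
Summed normalized counts on a log scale of 23 photoreceptor genes and of 19 platelet markers in each library, by day at even spacing, with circles for CT26 and triangles for B16. B16 photoreceptor sums go from 11230 to 21480 at day 0 to 223.4 to 461.3 at day 11, and B16 platelet sums from at most 35850 at day 0 to at least 60560 later.

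The mature neutrophil and suppressor cell lists at B16 day 11 were the only 2 of the list calls, over both models and all days, that held with an estimated correlation (counts in parentheses are adjusted over the list alone). Of 21 mature neutrophil genes, 17 rose and 1 fell (17 and 1), median log2 0.62, adjusted p = 4.12e-08 (adjusted p = 0.0192 with an estimated correlation). The chemokine receptor gene Cxcr2 went from 31120 ± 485 to 52710 ± 1829, and Mmp25 (1.69 ± 0.12) and Fpr1 (0.77 ± 0.05) rose. Of 22 suppressor cell effector genes, 16 rose and 0 fell (17 and 0), median log2 0.59, adjusted p = 2.28e-06 (adjusted p = 0.0409 with an estimated correlation). They included Hif1a (1.22 ± 0.08), Wfdc17 (1.12 ± 0.17), Il4ra (0.93 ± 0.09) and Clec4e (0.72 ± 0.06). Of 18 secondary granule genes, 13 rose and 1 fell (13 and 1), median log2 0.74, adjusted p = 2.78e-05 (adjusted p = 0.166 with an estimated correlation). Ngp reached 7735 ± 787, and Chil3 (1.73 ± 0.23), Ltf (1.45 ± 0.17) and Anxa1 (0.82 ± 0.05) rose. Of 24 immediate early and stress genes, 17 rose and 1 fell (17 and 1), median log2 0.45, adjusted p = 4.08e-06 (adjusted p = 0.166 with an estimated correlation). Jun reached 2207 ± 129, and Dusp1 (1.04 ± 0.09) and Fosb (0.92 ± 0.12) rose. Of 32 type I interferon response genes, 29 rose and 0 fell (30 and 0), median log2 0.97, adjusted p = 6.58e-11 (adjusted p = 0.456 with an estimated correlation). Oasl2 went from 25060 ± 5912 to 49660 ± 314, and Slfn4 (1.27 ± 0.10), Rtp4 (1.18 ± 0.09) and Zbp1 (1.12 ± 0.27) rose. Of 22 chemotaxis and adhesion receptor genes, 16 rose and 2 fell (17 and 2), median log2 0.59, adjusted p = 2.12e-06 (adjusted p = 0.052 with an estimated correlation). Of 20 G-CSF, GM-CSF and STAT3 signalling genes, 12 rose and 0 fell (12 and 0), median log2 0.33, adjusted p = 4.8e-05 (adjusted p = 0.194 with an estimated correlation).

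The other list calls of B16 day 11 were in platelet, NF-kB, ribosomal protein and oxidative phosphorylation genes (counts in parentheses adjusted over the list alone). Of 23 NF-kB cytokine and chemokine genes, 9 rose and 2 fell (9 and 2), median log2 0.28, adjusted p = 0.0144 (adjusted p = 0.396 with an estimated correlation). These included Cxcl2 (1.59 ± 0.16), Nfkbiz (0.98 ± 0.07) and Nfkb1 (0.89 ± 0.06). Of 19 platelet markers, 18 rose and 0 fell (19 and 0), median log2 2.41, adjusted p = 1.03e-06 (adjusted p = 0.502 with an estimated correlation). Of 81 cytosolic ribosomal protein genes, 0 rose and 65 fell (0 and 66), median log2 -0.56, adjusted p = 1.42e-19 (adjusted p = 0.396 with an estimated correlation). Of 38 oxidative phosphorylation genes, 1 rose and 24 fell (1 and 24), median log2 -0.33, adjusted p = 6.63e-06 (adjusted p = 0.502 with an estimated correlation). Rn45s stood at 59860 ± 5885 at day 8 and 137400 ± 20950 at day 11 and Lars2 fell at both days (-3.38 ± 0.11 and -1.72 ± 0.11). Members risen and fallen in lists not called were 2 and 1 of 6 (2 and 1) for primary granule and promyelocyte genes and 9 and 2 of 20 (9 and 2) for classical monocyte genes. Non-classical monocyte genes gave 6 and 2 of 14 (7 and 2) and NADPH oxidase genes 8 and 4 of 14 (8 and 4). MHC class II genes gave 2 and 3 of 13 (2 and 3). MHC class I genes gave 3 and 2 of 14 (3 and 2) and cell cycle genes 4 and 2 of 32 (2 and 0). Glycolysis and hypoxia genes gave 8 and 4 of 25 (8 and 4) and unfolded protein response genes 5 and 8 of 24 (5 and 8). Progenitor genes gave 3 and 0 of 11 (3 and 0) and B cell markers 1 and 5 of 14 (1 and 5). T cell markers gave 2 and 2 of 17 (1 and 2) and NK cell markers 1 and 0 of 9 (0 and 0). Erythroid markers gave 2 and 2 of 8 (2 and 2) and eosinophil markers 1 and 1 of 6 (1 and 1). Dendritic cell markers gave 0 and 4 of 9 (0 and 5) and melanocyte markers 0 and 2 of 4 (0 and 2). Epithelial markers gave 1 and 2 of 4 (1 and 2). B16 day 11 had 5451 called genes, 2856 higher and 2595 lower. Scaled to the same total, with a median shift of -0.14, 2049 were higher and 3559 lower, and with upper quartile scaling 2562 and 2883.

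Between successive days of B16 growth, Alox15, Ccr3 and H2-D1 moved at day 8 and back at day 11. From day 4 to day 8 Alox15 (5.19 ± 0.26), Ccr3 (3.39 ± 0.17) and Egr1 (3.32 ± 0.21) rose and Alas2 (-4.34 ± 0.29), H2-D1 (-0.94 ± 0.08) and Oasl2 (-0.86 ± 0.13) fell. From day 8 to day 11 Alox15 (-6.44 ± 0.23) and Ccr3 (-3.50 ± 0.15) fell and Egr1 (2.10 ± 0.18), H2-D1 (1.03 ± 0.07), Oasl2 (1.34 ± 0.12), Rn45s (1.19 ± 0.12) and Wnt4 (1.61 ± 0.27) rose, while Tubb1 was not called (log2 -1.01 ± 0.49, adjusted p = 0.129) unless day 0 replicate 3 was left out (adjusted p = 0.0493). These steps gave 3190 called genes (1510 higher, 1680 lower) and 4313 (2236 higher, 2077 lower). Under total scaling they gave 2694 higher and 904 lower around a median shift of 0.17, then 1016 higher and 4485 lower around -0.26. Upper quartile scaling gave 2669 higher and 1605 lower for the second step. Over all days 7705 B16 genes were called.

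**Figure D3:**
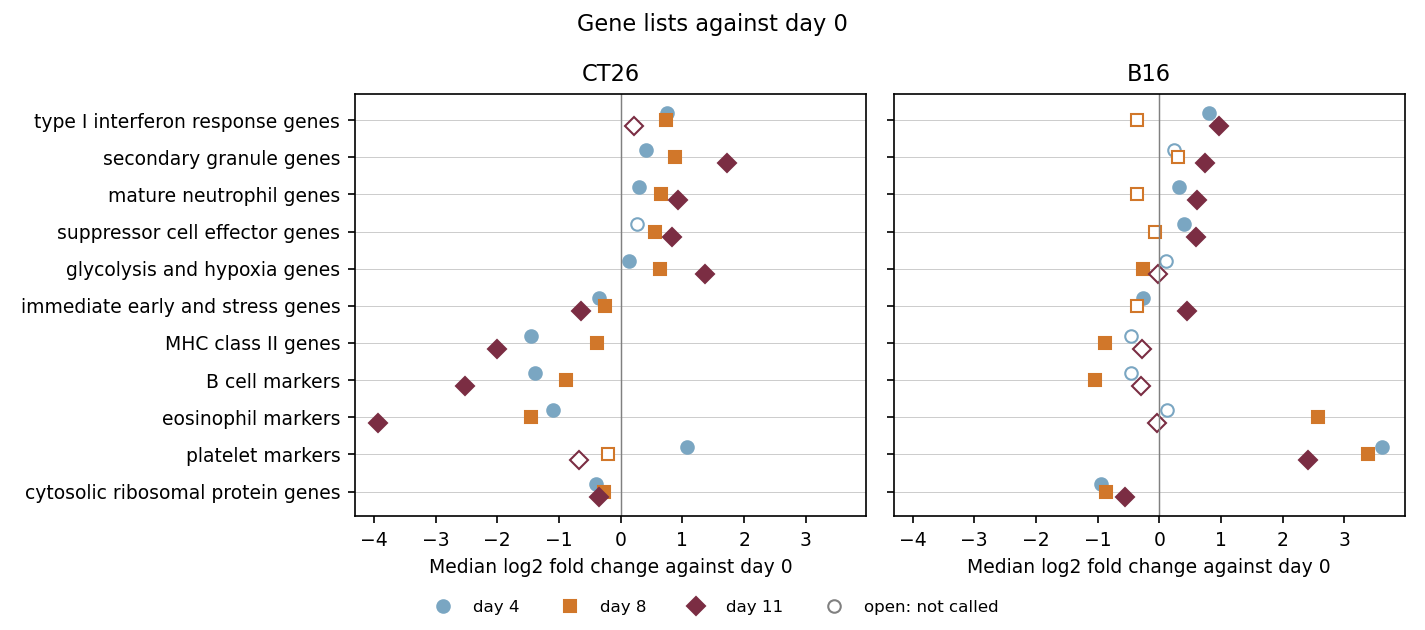
Median log2 fold change against day 0 of the members of 11 gene lists in CT26 and in B16, with circles for day 4, squares for day 8 and diamonds for day 11, filled where the list was called and open where not. Eosinophil markers stand at -3.93 at CT26 day 11 and at 2.57 at B16 day 8, and platelet markers at 3.60 at B16 day 4.

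Set side by side over the 10989 genes tested in both models, day 4 and day 11 changes went more often in the same direction, and less often in opposite ones, than independent calls would. At day 4, 369 genes were higher in both where independence gives 147, 164 were lower in both where it gives 80.5, and 87 were called in opposite directions. At day 8 the same direction was shared by 872, 539 higher where independence gives 485 and 333 lower where it gives 362, and opposite directions were seen in 944, 502 where independence gives 452 and 442 where it gives 389. At day 11 it was 2018 against 758, with 1273 higher in both where independence gives 718 and 745 lower where it gives 551. Across genes, which are not independent replicates, the log2 fold changes of the 2 models correlated with r of 0.276 (Spearman 0.287), -0.0159 (0.0135) and 0.186 (0.256) at the 3 days. These counts were not tested against a model of related genes. The day 4 same-direction count of 533 was 269 without CT26 day 0 replicate 1 and 980 without CT26 day 11 replicate 1, and the day 8 count was 562 without CT26 day 8 replicate 3.

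Whether the 2 models differ was tested for each gene in one edgeR fit to reads recovered from 19 libraries, a test added after the units of the files were known and with 2 and 3 CT26 libraries at days 8 and 11. Values are the B16 minus the CT26 log2 change. At day 11 Egr1 differed by 9.87 (adjusted p = 2.26e-13), Fosb by 6.98 (adjusted p = 8.57e-14) and Ptgs2 by 6.73 (adjusted p = 1.99e-12), and the hypoxia-induced hydroxylase gene P4ha1 by -3.59 (adjusted p = 2.71e-10) and Pfkl by -2.78. At day 8 Ccr3 differed by 5.03 (adjusted p = 1.21e-09), Ear1 by 5.70 and the phosphatase gene Inpp5j by 6.73, and the insulin-like growth factor binding gene Igfbp6 by -3.87. Nos2 differed by -7.29 at day 8 (adjusted p = 0.000268) and by -5.97 at day 11 (adjusted p = 0.000705), or by -11.48 and -10.14 without CT26 day 0 replicate 2. Leaving out a CT26 day 0 library leaves 1 there, assumed to vary like the others. S100a9 differed by -1.04 at day 8 (adjusted p = 3.77e-05) and by -0.39 at day 11 (adjusted p = 0.0461, or -0.67 without CT26 day 0 replicate 1), and without CT26 day 0 replicate 2 the day 11 call ended (-0.30, adjusted p = 0.196). S100a8 differed by -0.69 at day 8 (adjusted p = 0.0074) and was not called at day 11 (-0.16, adjusted p = 0.527). Arg1 was near 0 in B16, so the size of its difference is not given. It was not called at day 8 (adjusted p = 0.109) or day 11 (adjusted p = 0.0989), but was called at both with replicate number as a block (adjusted p = 0.00519 and adjusted p = 0.0073), without the filter (adjusted p = 0.0377 and adjusted p = 0.0305), in DESeq2 (adjusted p = 4.72e-06 and adjusted p = 9.15e-07) and without CT26 day 11 replicate 1 (adjusted p = 0.00297 and adjusted p = 0.00539). At day 8 it was also called with only the 2 days compared (adjusted p = 0.00499) and at day 11 without CT26 day 11 replicate 2 (adjusted p = 0.0415). Of 12655 genes 4616 differed at day 8 and 3754 at day 11, and the day 11 count was 2480 without CT26 day 0 replicate 2.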

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

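Of the tests in this part, the regrouping of libraries was written before the results were seen. All other tests of the 3 patterns below were chosen after.

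Libraries of 2 days were regrouped in the 10 ways that keep 3 against 3, and 10 splits cannot give a share below 0.05. The real grouping called the most genes, 1 of 10, at CT26 day 4 (1235, highest other 0), CT26 day 8 (3056, highest other 0), CT26 day 11 (5721, highest other 0), CT26 day 8 against 4 (1522, highest other 0), CT26 day 11 against 8 (2375, highest other 4), B16 day 8 (6676, highest other 0), B16 day 11 (5451, highest other 0) and B16 day 11 against 8 (4313, highest other 0). For lists the real grouping ranked 1 at CT26 day 4 (14, highest other 11), day 8 (15, highest other 12) and day 11 (17, highest other 14), 2 at B16 day 8 (9, highest other 9) and 4 at B16 day 11 (11, highest other 15). These ranks cannot tell the number of lists called from regrouped libraries in either model. For CT26 over all days, 1 of 100 groupings, the real one itself, called as many genes (5661, highest other 3859).

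The models gave 4616 and 3754 genes with different effects at days 8 and 11 in the joint edgeR test. B16 minus CT26 effects at day 8 were Ccr3 5.03, Nr4a1 2.11, Anxa6 1.87, Ear1 5.70, Inpp5j 6.73, Sema6b -2.63, Igfbp6 -3.87, Lrg1 -2.48, Wfdc18 -5.50, Wfdc21 -2.65, Nos2 -7.29, S100a8 -0.69 and S100a9 -1.04. At day 11 they were Fosb 6.98, Egr1 9.87, Ptgs2 6.73, Nr4a1 2.99, Ppp1r15a 2.77, P4ha1 -3.59, Pfkl -2.78, Egln3 -2.23, Crispld2 -2.38, Pgam1 -1.87, Nos2 -5.97 and S100a9 -0.39. Model, mouse strain and any batch go together, so which of them the differences follow cannot be known.

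Photoreceptor transcripts stood at 11230 to 21480 summed counts in B16 day 0 libraries and at 287 to 1020 in CT26 day 4 libraries. Within B16 day 4 they stood at 3809 and 24390, and within day 8 at 1621 to 6991. One explanation is RNA from retinal tissue in the libraries. With day means removed over 8 B16 libraries, the SD of a gene's log2 distance to the mean of the other photoreceptor genes was 0.174 of the gene's own SD (median of 23 genes), against at least 0.924 in 200 sets of other genes of like abundance. This is consistent with one source mixed in at different amounts. The normalization factors differ by at most 1.464 times, far less than the sums, which argues against them as the cause. How retinal RNA would have entered, and whether blood cells could turn on these genes together, stay open.

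Arg1 and tissue macrophage genes rose in the CT26 day 8 and day 11 libraries. The same measure of distance, over the 6 libraries with day means removed, was 0.197 (median of Arg1 and 13 macrophage genes), against at least 0.875 in 200 sets of other genes, which is consistent with cells of another type, tissue macrophages, at varying shares. Factors of at most 1.301 argue against normalization, and without CT26 day 11 replicate 1 Arg1 was still 8.60 above day 0 and 13 of 13 macrophage genes rose. Blood cells that turned on both sets of genes would give the same ratio, and no test here separates the 2.

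Platelet transcripts rose in the B16 libraries of days 4, 8 and 11. The same measure of distance over 11 B16 libraries was 0.241 (median of 19 genes), against at least 0.802 in 200 sets of other genes, which is consistent with platelets or megakaryocyte-lineage cells carried with the separated cells. A lower share of the main cell type would raise other types alike, and the highest other median at day 4 was 1.11 against 3.60 for platelets. Factors of at most 1.464 argue against normalization. Whether the blood held more platelets, or more of them stayed with the cells, is open.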

How the results depend on the processing

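Total scaling, edgeR with TMM on recovered reads, limma on 8 CT26 libraries and the joint test were added after the units were known, and the other settings were chosen before. Of the counts recomputed, 90 moved by more than 1.5 times, and of the gene and list values 19 reversed, 40 became called and 604 lost a call. Where no reason is given the cause was not tested. Limits are 2 or 3 libraries per group, one normalization per model (except the joint test) and a shared day 0 group per model. With the estimated correlation the lists called were 0, 0 and 0 in CT26 and 0, 0 and 2 in B16 at days 4, 8 and 11. With fry, which asks another question, they were 23 at CT26 day 8, 18 at B16 day 8 and 19 at B16 day 11. A minimum absolute log2 fold change of 1 gives fewer genes by construction. It left 266, 814 and 1925 in CT26 and 1221, 2302 and 1492 in B16 against day 0, and 380 and 592 (CT26) and 522 and 857 (B16) between successive days. For B16 minus CT26 effect (joint count test), day 8 against day 0, it left 2265 and for B16 minus CT26 effect (joint count test), day 11 against day 0, 1779. In agreement of the models, day 4 against day 0, it left 46, in agreement of the models, day 8 against day 0, 68 and in agreement of the models, day 11 against day 0, 228. Fitting only the 2 days compared gave 2352 for CT26 day 4 against day 0, 2597 for CT26 day 8 against day 4, 1483 for CT26 day 11 against day 8 and 807 shared at day 4.

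The count tests use 8 CT26 libraries, 1 of them of day 4, and limma on the same 8 also falls, so fewer libraries account for most of the loss. Counts follow in the order CT26 day 4 against day 0, CT26 day 8 against day 0, CT26 day 8 against day 4, CT26 day 11 against day 8, CT26 any day, agreement of the models, day 4 against day 0, and agreement of the models, day 8 against day 0. That limma fit gave 58, 1245, 270, 925, 3144, 27 and 321. edgeR gave 74, 1405, 283, 949, 3359, 33 and 368 with TMM, 57, 1234, 221, 873, 3156, 24 and 303 with RLE, and 71, 1409, 295, 996, 3374, 31 and 344 with upper quartile. limma-voom gave 89, 1479, 313, 902, 3343, 34 and 384. DESeq2 gave 212, 1234, 335, 803, 2918, 123 and 330, with 3330 for CT26 day 11 against day 0 and 1293 for agreement of the models, day 11 against day 0. The CT26 day 4 platelet median turned to -0.165 (limma on 8), -0.185 (TMM), -0.159 (RLE), -0.249 (upper quartile) and -0.184 (voom). S100a9, CT26 day 4 against day 0, turned to -0.12, -0.15, -0.13, -0.22, -0.14 and, in DESeq2, -0.13, and S100a8, CT26 day 4 against day 0, to -0.061 with upper quartile. Under total scaling the S100a9 value was -0.049 and S100a8 at B16 day 8 was 0.086.

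Leaving out each library in turn gave 626 to 2419 genes for CT26 day 4 against day 0 (669, 704, 724 and 755 among them), 1583 to 3428 for CT26 day 11 against day 8 and 2782 to 4322 for B16 day 4 against day 0. Shared directions went from 269 to 980 at day 4 and from 562 to 1129 at day 8. Joint test counts went from 2480 to 3966 at day 11. Uncalled values crossed 0. At CT26 day 4 Arg1 went from -0.86 to 0.36 (0.15 without day 4 replicate 1) and S100a9, CT26 day 4 against day 0, from -0.063 to 0.23. S100a8 in B16 went from -0.048 to 0.013 at day 4 and from -0.12 to 0.046 at day 8. Replicate number as a block moved no count by 1.5 times. Residuals of same-number libraries correlated at a median of -0.0475 in CT26 and -0.0021 in B16. With 2 or 3 libraries per day this cannot exclude pairing.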

Other observations

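Fibroblast genes, a group collected after the values were seen, rose in CT26 at the later days. Of 6 tested, 1 rose at day 4, 6 at day 8 and 5 at day 11, and 0 fell. Col1a2 was listed at 0 on days 0 and 4 and stood at 37.4 ± 29.0 at day 8 and 18.1 ± 13.1 at day 11 (mean ± SD, 3 libraries). Col3a1 stood at 0.332 ± 0.574 at day 0, 42.8 ± 31.6 at day 8 (log2 4.68 ± 0.65) and 25.9 ± 12.1 at day 11 (log2 4.33 ± 0.65). These are low counts in cells that are not known for making collagen.

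Rn45s, Lars2, Mir6236 and Mir6240, grouped as ribosomal RNA loci after the values were seen, fell in B16 at every later day, 4 of 4 each time, around medians of -2.56, -3.18 and -1.66. In CT26 3 of 4 fell at day 4 and none at days 8 and 11. Of these, Rn45s is a ribosomal RNA gene, which poly-A selection keeps irregularly, and its shares at B16 day 0 set that group apart from the others. Tissue macrophage genes in B16, 5 tested, rose in 2, 5 and 1 cases at days 4, 8 and 11.

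Across the 6 CT26 libraries of days 8 and 11, 6 relations to the mean log2 value of the tissue macrophage genes were computed after the values were seen. Arg1 followed it with Pearson r 0.992 (exact permutation p = 0.00139, adjusted 0.00834) and Spearman correlation 1 (exact permutation p = 0.00278), and r was 0.985 without the 2 farthest libraries. These values include the step from day 8 to day 11. With day means removed r was 0.985 (Arg1), 0.982 (Saa3) and -0.883 (S100a9). None passed (each exact permutation p = 0.0278, the lowest that 36 arrangements within days allow, adjusted 0.0556). Saa3 followed it with r 0.987 (exact permutation p = 0.00278, adjusted 0.00834), Spearman correlation 0.943 (exact permutation p = 0.0167) and 0.914 without the 2 farthest. Nos2 (r 0.628, exact permutation p = 0.178), Lipg (0.15, p = 0.775), fibroblast genes (0.187, p = 0.782) and S100a9 (-0.059, p = 0.914) passed neither way. Within day 8 and day 11, 3 libraries each and too few to test, r was 0.977 and 1 (Arg1), 0.961 and 1 (Saa3), -0.88 and -0.196 (Nos2), -0.982 and -0.849 (Lipg), 0.936 and 0.63 (fibroblast genes) and -0.966 and -0.988 (S100a9).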
